A study of Mus musculus with 12 samples.

How the data were processed

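Total RNA from the brains of 12 mice was measured on 12 arrays of 1 colour, 1 per mouse, with 3 mice in each of the 4 groups formed by age (4 or 22 months) and treatment (saline or LPS at 0.33 mg/kg, 4 h before collection). Groups and mouse numbers were taken from the sample titles. The numbers within a group only name the mice. The numbers in the titles run consecutively through the groups, so any order of handling and the group cannot be told apart.

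The value table holds the authors' deposited signal intensity for 45101 probe sets on a linear scale, made with GCOS 1.1 per the submitters' processing notes. The mean of each array after removal of 2% of the probe sets at each end was 150.0, so the authors had scaled the arrays to a common level. The array type and the probe set algorithm are not given in the sources used here. The 4 tables of comparisons hold the authors' unadjusted and adjusted p-values and, per the file headers, a fold change. The authors' fold change is a signed score, a ratio where above 1 and minus the inverse ratio where below, as its values show. The authors' test and filter behind these tables are not given in the sources used here. The tables for LPS in adult and in aged mice are identical in all 1357 listed probe sets, so 3 of the 4 are distinct.

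Gene symbols came from these tables only, since no annotation of the array was used here. Of the 2709 probe sets the tables list, 2692 carry 1 symbol and 17 none. Symbols were brought up to date through the synonyms of the reference gene table of assembly GRCm38.p6, which changed those of 461 probe sets. The synonym was ambiguous for 22 symbols, which were kept as deposited (C4 among them), and 13 were not found. This left 2491 distinct symbols and 42409 probe sets without a name, which were tested and counted but not named.

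Values were transformed as log2(signal + 32), so a fold change understates the change of dim genes. The 64 control probe sets were left out. For each symbol the probe set with the highest mean over the 12 arrays was kept, which gave 44836 features. This rule reached only named probe sets, so unnamed ones can measure a gene more than once. The 30% of features with the lowest mean, under a signal of about 16.9, were left out, which removed 43 named genes. The remaining 31385 had a median signal of 90.5. They were tested in limma 3.58.1 under R 4.3.3 with a mean for each of the 4 groups and 1 shared spread per feature over all 12 arrays (8 residual and 4.73 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 7 comparisons were LPS against saline at each age, aged against adult in each treatment, the difference of the LPS effect between ages, and both effects averaged. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

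Groups, tests, 31 gene lists and the alternatives were fixed before the data were examined. Of 438 listed genes 227 were named, and 27 lists with at least 3 named members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. All list tests used named features only. A list member was named only if the authors' tables of probe sets selected on these same arrays held it. The list p-values, medians and counts are therefore conditional on that selection. Camera with an estimated correlation and fry were alternatives, and of 71 list calls over the 7 comparisons 18 held with the estimated correlation. The rule for the genes named in the text took, in each comparison, the 10 largest rises and the 10 largest falls among genes that passed and whose groups did not overlap (within each stratum for averaged comparisons, with no such condition for the difference), or the 5 smallest p-values where fewer than 5 passed. It added 17 genes stated in advance, of which 10 were named, and up to 4 members by smallest p of lists that shifted or held genes that passed. The text gives some of these. Exceptions chosen after their values were seen were the hepatocyte transcripts, the acute-phase genes Hp and Saa1, the olfactory bulb markers and the genes quoted only from the authors' tables. Those cell type lists, of 32 hepatocyte transcripts and 7 bulb markers, were also written after the data were seen. Of these 23 and 4 were tested, and the others had no symbol from the authors' tables or were dim. The authors' table for age in saline mice lists 22 of the 32 hepatocyte transcripts as higher. The tested ones were thus in part selected for high values in aged mice.

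The fits were tested on simulated data with the real means and spreads of the features. With 2-fold changes the share recovered was 58.2% for LPS in adult mice, 44.8% in aged mice, 59.7% and 50.7% for age in saline and LPS mice, 16.4% for the difference of the LPS effect, and 80.6% and 79.1% for the averaged effects of LPS and age. A list shifted by 0.5 was called in all 7 comparisons, with 0 other lists. The simulated features varied independently of each other, so this does not show how often lists of correlated genes are called wrongly. The alternatives were a shift of the arrays to the same median, quantile normalization, a pseudocount of 1 or of 4 times 32, no filter or the lowest 50% left out, the mean over the probe sets of a gene or all probe sets separately, a minimum change of 1.5-fold, an intensity trend with robust spread, array weights, only the groups compared, the mouse number as a block, the unmoderated test, and each array left out in turn. Added after the data were seen were 2 covariates (hepatocyte transcripts, bulb markers) and the joint removal of 2 arrays. For single genes stated in advance, exact two-sided permutation tests of 3 against 3 mice were run, whose smallest p is 0.1. The results of 1 further gene are not reported here.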

Results

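The series measured gene expression in the brains of 12 male mice from an in-house BALB/c colony, with 3 mice in each of 4 groups. Adult mice were 4 months old and aged mice 22 months old. Each mouse was injected in the peritoneum with saline or with 0.33 mg/kg of lipopolysaccharide (LPS), a component of the bacterial outer membrane that activates innate immune cells. Brains were collected after 4 h, and the RNA of each brain was hybridised to its own array of 45101 probe sets. By its title, the study asked whether peripheral immune activation inflames the aged brain more than the adult brain. The median signal per array lay between 39.2 and 47.8, and pairs of arrays within a group correlated across probe sets at r between 0.961 and 0.968. The 3'-to-5' signal ratio of the control probe sets lay between 0.749 and 0.919 for Gapdh and between 1.29 and 1.73 for actin. The 18S ribosomal RNA control probe set gave 88.1 on the array of aged LPS mouse 3 and 116.2 on that of adult LPS mouse 3, below the 170.5 to 262.8 of the other 10 arrays. Of the 6 LPS arrays 4 lay below 195.5, the lowest 18S value of the 6 saline arrays. Of the 31385 features tested, 2448 carried a gene symbol. All symbols came from the authors' own tables of probe sets selected on these samples, so the share of named genes that changed is not independent evidence of how widespread a change was. The gene list tests used only these named genes, so their p-values, medians and counts depend on that selection too. With 3 mice per group, the number of arrays limits the precision of every value.

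In adult mice, LPS raised genes of the acute-phase, chemokine and interferon responses within 4 h. Lcn2, an iron-sequestering acute-phase protein, had the largest rise of a named gene, from a signal of 12.9 ± 10.5 to 1876 ± 969 (SD, n = 3), which was 5.32 ± 0.43 (SE) on the log2 scale. The chemokine genes Cxcl11, Cxcl10 and Ccl12, whose products attract T cells and monocytes, rose by 3.83 ± 0.44, 2.99 ± 0.48 and 2.66 ± 0.31 log2. Cebpd, a transcription factor of the acute-phase response, rose by 2.62 ± 0.24, and Icam1, an adhesion molecule for leukocytes on activated endothelium, by 2.52 ± 0.34. The interferon-induced GTPase genes Gbp2b and Gbp2 rose by 2.96 ± 0.34 and 2.44 ± 0.29, and the interferon-induced genes Ifit1 and Ly6a by 2.51 ± 0.32 and 2.51 ± 0.33. These 10 were the named genes with the largest rises among those that passed with no overlap between the groups. In total, 143 of 31385 features rose and 35 fell in limma at an adjusted p under 0.05, of which 75 and 23 had symbols. Of these, 112 rose and 20 fell at least 2-fold. The total of 178 came to 89 (79 rose and 10 fell) without adult LPS mouse 3, to 112 (95 and 17) without adult saline mouse 1 and to 112 (100 and 12) without adult saline mouse 3. The falls also came to 20, 16, 19 and 22 without adult LPS mouse 2, adult saline mouse 2 and aged LPS mice 1 and 2. The total was 318 with an intensity trend and robust spread in limma. Adding 1 instead of 32 before the logarithm left 83 features and ended the calls of Icam1 (adjusted p = 0.178), Ccl12 and Ifit1 (0.128 each), Cxcl10 (0.114) and Gbp2 (0.0598). The Cxcl10 call also ended without adult saline mouse 3, at an adjusted p of 0.0573, and with the intensity trend (0.0541). For Cxcl11 a dimmer probe set gave 0.60, at an adjusted p of 0.265.

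**Figure D1:**
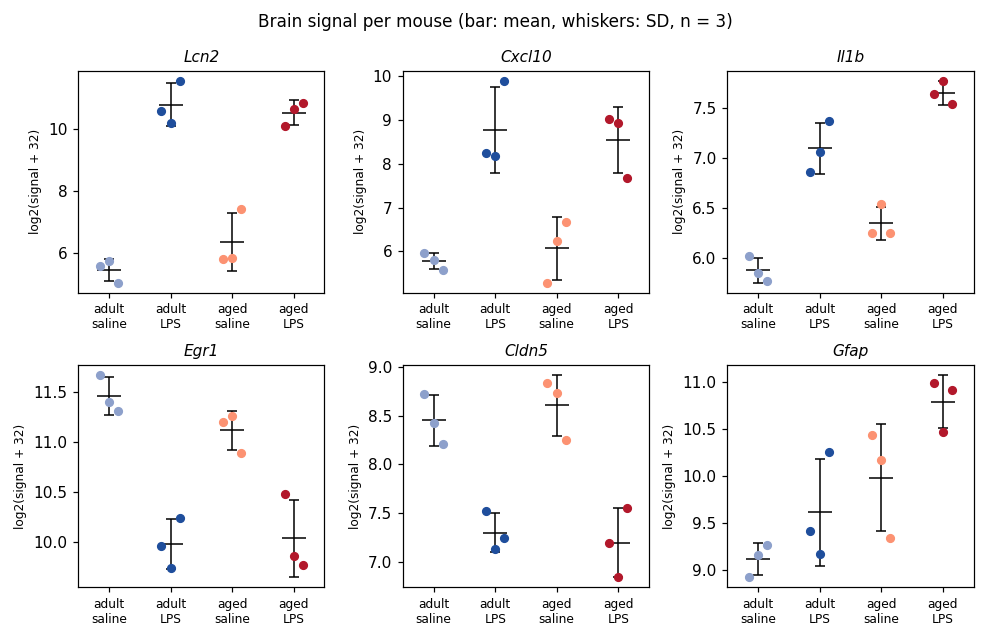
Each point is the log2(signal + 32) of 1 mouse for Lcn2, Cxcl10, Il1b, Egr1, Cldn5 and Gfap in the 4 groups, with a bar at the mean and whiskers of 1 SD (n = 3). Lcn2 lay higher in each LPS mouse than in any saline mouse of the same age, and Egr1 lay lower.

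Among the gene lists fixed before the data were examined, the interferon-stimulated genes had the smallest camera p at the preset correlation in adult mice. Of 23 named members, 11 rose, none fell and 12 did not pass, and adjusted over the list alone 18 rose and 1 fell. Isg15, a ubiquitin-like modifier, rose by 2.29 ± 0.20 log2, Ifitm3, a membrane protein that restricts viral entry, by 2.13 ± 0.23, and Usp18, the protease that removes Isg15, by 1.92 ± 0.21. The list's median was 1.12 (camera adjusted p = 1.04e-16). Of 13 glucocorticoid-responsive genes, 8 rose and 5 did not pass, and 12 rose adjusted over the list alone. They included the cell-cycle inhibitor Cdkn1a (1.82 ± 0.22) and the metallothionein Mt2 (1.64 ± 0.19), and the list's adjusted p was 3.02e-13. Without adult LPS mouse 3, 4 of them rose. Of 16 acute-phase genes and STAT3 targets, 5 rose and 11 did not pass, with 10 adjusted over the list alone (adjusted p = 5.27e-09). Besides Lcn2 and Cebpd they included Osmr, the oncostatin M receptor, at 1.61 ± 0.17. Of 12 genes of Toll-like receptor and NF-kB signalling, 3 rose and 9 did not pass, with 8 adjusted over the list alone (adjusted p = 8.83e-07). Cd14, a co-receptor for LPS, rose by 1.86 ± 0.24 and Nfkbia, the inhibitor of NF-kB, by 1.51 ± 0.15, while another probe set of Nfkbia gave 0.67 (adjusted p = 0.0906). Of 8 endothelial activation genes, 4 rose, among them the adhesion genes Selp (1.80 ± 0.20) and Vcam1 (1.36 ± 0.17), with 6 adjusted over the list alone (adjusted p = 2.07e-06). Of 4 cytokine genes, Csf3 (1.36 ± 0.15) and Il1b (1.22 ± 0.16) rose, and all 4 did adjusted over the list alone (adjusted p = 0.000129). These 6 lists also passed with an estimated correlation, at adjusted p between 0.0176 and 0.0383.

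The remaining lists that shifted upward in adult mice passed in camera with the preset correlation and not with an estimated one, and passed in fry, at adjusted p of 0.000222 to 0.00897. Of 9 chemokine genes, 4 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.000154, and adjusted p = 0.117 with an estimated correlation). The 4 were Cxcl11, Cxcl10, Ccl12 and the neutrophil attractant Cxcl1 (2.23 ± 0.36), whose call ended without adult LPS mouse 3 at an adjusted p of 0.0691 and was 0.213 after adding 1 instead of 32. The fall was that of Cxcl12 (-1.31 ± 0.23), whose call ended without any 1 of the 6 adult mice (adjusted p of 0.0547 to 0.125) and after adding 1 (0.215). Of 10 reactive astrocyte genes, 3 rose, namely Lcn2, Osmr and Cd14, and 6 did adjusted over the list alone (adjusted p = 1.19e-05, and adjusted p = 0.0681 with an estimated correlation). Of 3 neutrophil and monocyte markers, S100a9, a calcium-binding protein abundant in neutrophils, rose by 1.70 ± 0.23, while S100a8 gave 1.66 ± 0.34 at an adjusted p of 0.0545, and 2 of the 3 rose without adult LPS mouse 2, adult saline mouse 2 or aged saline mouse 2 or 3. The list had an adjusted p of 0.00417, and an adjusted p of 0.0787 with an estimated correlation. Of 7 complement genes 1 rose, C2 (1.40 ± 0.25), and 4 did adjusted over the list alone (adjusted p = 0.00982, and adjusted p = 0.170 with an estimated correlation). The C2 call ended without adult LPS mouse 2 or 3 or adult saline mouse 1, 2 or 3 (adjusted p of 0.0752 to 0.125) and after adding 1 (0.0844). Of 12 genes of aged or activated microglia 1 rose, the immunoglobulin receptor gene Fcgr2b (0.82 ± 0.15), and 2 did adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.0911 with an estimated correlation). The Fcgr2b call ended without adult LPS mouse 1 or 3, adult saline mouse 1 or 3 or aged LPS mouse 1 (adjusted p of 0.0511 to 0.134). It also ended with the mean of its probe sets (0.0790), without the filter on dim features (0.0517) and with only the groups compared in the fit (0.156), and its other probe set gave 0.73 (0.394). Of 7 sickness mediators and their receptors none passed, and 4 rose adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.0787 with an estimated correlation). That last shift ended without adult LPS mouse 1 or 2, at an adjusted p of 0.0603 to 0.0710, and with the lowest 50% of the features left out (0.103). Of the genes stated in advance, Ccl2 gave 1.05 ± 0.34 (adjusted p = 0.333), Tlr2 0.96 ± 0.23 (0.130), the prostaglandin synthase gene Ptgs2 0.69 ± 0.21 (0.259), and Gfap, an astrocyte filament protein, 0.50 ± 0.30 (0.751). The microglial genes Cd68 and Aif1 gave 0.05 ± 0.17 and -0.00 ± 0.23. A two-sided exact permutation test of 3 against 3 mice cannot go below p = 0.1, which it gave for Lcn2, Cxcl10, Il1b, Cd14, Tlr2 and Ptgs2.

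The genes that fell in adult mice included activity-dependent and endothelial transcripts. Egr1, a transcription factor induced by neuronal activity, fell by 1.48 ± 0.21 log2 (adjusted p = 0.00467), and Ppargc1a, a coactivator of mitochondrial biogenesis, by 1.45 ± 0.21. Nr4a3, another activity-dependent transcription factor, fell by 1.19 ± 0.16. Of 14 immediate-early genes, 3 fell and 11 did not pass, and 10 fell adjusted over the list alone (median -0.97, camera adjusted p = 3.51e-06, and adjusted p = 0.159 with an estimated correlation). Of 11 brain endothelial markers, 5 fell and 1, Ly6a, rose, and adjusted over the list alone 7 fell (adjusted p = 0.00217, and adjusted p = 0.0698 with an estimated correlation). Those that fell included Slco1a4, an organic anion transporter of the blood-brain barrier (-1.39 ± 0.23), and Cldn5, a tight junction protein (-1.15 ± 0.22). The count of 5 came to 0 without adult LPS mouse 3 or adult saline mouse 3, to 1 without adult saline mouse 2 or aged LPS mouse 1, to 2 without adult LPS mouse 1 or 2 or adult saline mouse 1, and to 3 without aged saline mouse 1 or 3. Of 7 microglia markers, Cx3cr1, the fractalkine receptor, fell by 1.33 ± 0.22, while Gpr34 gave -1.22 ± 0.25 (adjusted p = 0.0505) and P2ry12 -0.82 ± 0.21 (0.141). The microglia marker list had a median of -0.49 and an adjusted p of 0.0426, and an adjusted p of 0.170 with an estimated correlation. Its call also ended with the intensity trend (0.0504), with the lowest 50% of the features left out (median -0.25, 0.155), and after adding 1 (0.0611) or 4 times as much as 32 (0.0665). Of 10 heat-shock and chaperone genes none passed, and 2 fell adjusted over the list alone (adjusted p = 0.0311, and adjusted p = 0.316 with an estimated correlation). Calls that ended with 1 array left out were Slco1a4 (adult LPS mouse 3 and adult saline mouse 3, adjusted p of 0.0619 to 0.0719), Cx3cr1 (adult LPS mouse 3 and adult saline mice 1, 2 and 3, 0.0501 to 0.0800), Cldn5 (adult LPS mice 2 and 3, adult saline mice 1, 2 and 3 and aged LPS mouse 1, 0.0542 to 0.148), the microglia list (adult LPS mice 1 and 2 and adult saline mouse 2, 0.0532 to 0.118) and the heat-shock list (adult LPS mouse 2 and adult saline mouse 3, 0.0635 to 0.0742). Without aged saline mouse 2 or 3, 2 microglia markers fell. Adding 1 instead of 32 ended the calls of Slco1a4 (0.0687), Cx3cr1 (0.0854) and Cldn5 (0.119), with only the groups compared in the fit Slco1a4 and Cldn5 had 0.0543 and 0.0505, and without the filter on dim features Cldn5 had 0.0514.

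In aged mice LPS raised acute-phase, chemokine and interferon-induced genes. Lcn2 rose from a signal of 63.2 ± 66.8 to 1481 ± 385 (SD, n = 3), a change of 4.17 ± 0.43 (SE) on the log2 scale. Cxcl11 rose by 3.10 ± 0.44, Cebpd by 2.68 ± 0.24, Ccl12 by 2.67 ± 0.31, Gbp2b by 2.52 ± 0.34, Ifit1 by 2.45 ± 0.32, Gbp2 by 2.38 ± 0.29 and Ly6a by 2.33 ± 0.33. Cxcl10 and Slfn4, an interferon-induced regulator of myeloid cells, rose by 2.47 ± 0.48 (adjusted p = 0.0409) and 2.19 ± 0.33 (0.00924). Il1b rose by 1.30 ± 0.16 (adjusted p = 0.00303). In limma 112 features rose and 58 fell, of which 57 and 26 had symbols, and 96 rose and 44 fell at least 2-fold. The total of 170 came to 72 (58 rose and 14 fell), 95 (69 and 26) and 110 (78 and 32) without aged saline mice 2, 1 and 3, to 85 (64 and 21) and 83 (53 and 30) without aged LPS mice 1 and 2, and to 287 (130 and 157) without adult LPS mouse 3. It was 451 with the intensity trend. The Cxcl10 call ended without any of 8 arrays (adult and aged saline mice 1, 2 and 3 and aged LPS mice 1 and 2, adjusted p of 0.0539 to 0.151), without the filter on dim features (0.0542), with only the groups compared in the fit (0.0637) and with the intensity trend (0.0902), and the Slfn4 call without aged LPS mouse 1 or aged saline mouse 2 (0.0504 to 0.0542). Adding 1 instead of 32 left 84 features and ended the calls of Lcn2 (0.0828), Cxcl11 (0.0963), Ccl12 (0.0892), Ifit1 (0.0970), Gbp2 (0.0812), Gbp2b (0.0604), Ly6a (0.0502), Cxcl10 (0.159) and Slfn4 (0.185).

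Interferon-stimulated and endothelial activation genes shifted upward in aged mice. Of 23 interferon-stimulated genes, 9 rose and 14 did not pass, and 21 rose adjusted over the list alone, with a median of 1.09 (camera adjusted p = 7.09e-15). Usp18 and Isg15 rose by 1.86 ± 0.21 and 1.76 ± 0.20 log2. Of 8 endothelial activation genes, 4 rose and 6 did adjusted over the list alone, among them Selp (1.98 ± 0.20), Vcam1 (1.18 ± 0.17) and Angptl4, an inhibitor of lipoprotein lipase (1.79 ± 0.21). Another probe set of Vcam1 gave 1.02 (adjusted p = 0.0595). This list had an adjusted p of 9.92e-06, and it and the interferon list also passed with an estimated correlation, at an adjusted p of 0.0253 each. Of 16 acute-phase genes and STAT3 targets, 6 rose, including Osmr (1.87 ± 0.17) and the transcription factor Cebpb (1.44 ± 0.18), and 9 did adjusted over the list alone (adjusted p = 1.63e-07). Of 12 genes of Toll-like receptor and NF-kB signalling, 4 rose, including the NF-kB cofactor Bcl3 (1.61 ± 0.23) and Nfkbia (1.12 ± 0.15, and 0.33 at an adjusted p of 0.435 on another probe set), and 9 did adjusted over the list alone (adjusted p = 1.73e-06). Without aged saline mouse 1 or 2, 2 of them rose. Of 13 glucocorticoid-responsive genes, 4 rose, namely Cdkn1a, Mt2, the leucine zipper gene Tsc22d3 and the kinase gene Sgk1 (1.40 ± 0.21), and 12 did adjusted over the list alone (adjusted p = 5.26e-08). The count of 4 came to 1 without aged LPS mouse 1, 2 or 3 or aged saline mouse 2 or 3, and to 2 without adult LPS mouse 1, adult saline mouse 3 or aged saline mouse 1, with Cdkn1a, Mt2 and Tsc22d3 at adjusted p up to 0.135, 0.0984 and 0.123. These 3 calls also ended after adding 1 instead of 32 (0.123, 0.0831 and 0.103), and with only the groups compared in the fit Sgk1 had 0.0616. Of 10 reactive astrocyte genes 4 rose, and 7 did adjusted over the list alone (adjusted p = 1.73e-06), while 2 rose without aged LPS mouse 2 or aged saline mouse 1, 2 or 3. With an estimated correlation these 4 lists had an adjusted p = 0.0533 each. Of 9 chemokine genes 3 rose and 1 fell, and 6 and 1 did adjusted over the list alone (adjusted p = 0.00282, and adjusted p = 0.218 with an estimated correlation). Cxcl1, not among these 3, gave 1.24 ± 0.36 (adjusted p = 0.187), while its other probe set rose by 1.72 (0.0138).

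Of 4 cytokine genes in aged mice, Il1b and Csf3 (1.14 ± 0.15) rose, also adjusted over the list alone (camera adjusted p = 0.00309, and adjusted p = 0.0743 with an estimated correlation). Of 3 neutrophil and monocyte markers, S100a9 (1.52 ± 0.23) and S100a8 (2.13 ± 0.34) rose (adjusted p = 0.00478, and adjusted p = 0.0858 with an estimated correlation). None of 7 complement genes passed, and 2 rose adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.230 with an estimated correlation). None of 12 genes of aged or activated microglia passed, and 4 rose adjusted over the list alone (adjusted p = 0.0455, and adjusted p = 0.176 with an estimated correlation). Among the genes stated in advance, Cd14 rose by 1.44 ± 0.24 (adjusted p = 0.0172), while Tlr2 gave 1.03 ± 0.23 (0.0846), Ccl2 0.97 ± 0.34 (0.287), Gfap 0.80 ± 0.30 (0.341), Ptgs2 0.65 ± 0.21 (0.227), Cd68 -0.08 ± 0.17 (0.909) and Aif1 -0.35 ± 0.23 (0.606). Calls ended with 1 array left out for S100a8 (aged LPS mouse 2 and aged saline mice 1 and 2, adjusted p of 0.0628 to 0.0730), Cd14 (aged LPS mice 1 and 2 and aged saline mice 1, 2 and 3, 0.0602 to 0.0920), the complement list (aged LPS mouse 3 and aged saline mouse 1, 0.0716 to 0.118) and the microglia list (aged LPS mice 1 and 3 and aged saline mouse 3, 0.0542 to 0.116). That list also missed with array weights (0.0510), with the arrays shifted to the same median (0.0545) and with the lowest 50% of the features left out (0.0735). Adding 1 instead of 32 ended those of Cd14 (0.0963), S100a8 (0.128) and S100a9 (0.0745).

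In aged mice Cxcl12, a chemokine made by endothelial and stromal cells, fell by 2.36 ± 0.23 log2 (adjusted p = 0.000992), the largest fall by the rule for named genes. Ramp2, a subunit of the adrenomedullin receptor of vessels, fell by 1.89 ± 0.28 (adjusted p = 0.00791), and Ppargc1a by 1.74 ± 0.21. Map1b, a neuronal microtubule protein, fell by 1.68 ± 0.27, and the kinase Wnk1 by 1.49 ± 0.25. Of 11 brain endothelial markers, 2 fell, Slco1a4 (-1.50 ± 0.23) and Cldn5 (-1.41 ± 0.22), and Ly6a rose. Adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.000975, and adjusted p = 0.0533 with an estimated correlation). Of 14 immediate-early genes, Egr1 fell by 1.08 ± 0.21 (adjusted p = 0.0390), and 4 fell adjusted over the list alone (adjusted p = 0.00607, and adjusted p = 0.396 with an estimated correlation). In fry this list had an adjusted p of 0.0801. None of 6 neurogenesis and proliferation genes passed, and 1 fell adjusted over the list alone (median -0.45, adjusted p = 0.0247, and adjusted p = 0.176 with an estimated correlation). Calls ended with 1 array left out for Slco1a4 (aged LPS mouse 1 and aged saline mouse 2, adjusted p of 0.0519 to 0.0542), Cldn5 and Map1b (aged LPS mice 1 and 2 and aged saline mice 1 and 2, 0.0503 to 0.0590 and 0.0547 to 0.0656), Wnk1 (aged LPS mice 1, 2 and 3 and aged saline mice 2 and 3, 0.0526 to 0.0853), Egr1 (adult LPS mouse 1, adult saline mice 2 and 3, aged LPS mice 2 and 3 and aged saline mice 1, 2 and 3, 0.0561 to 0.165) and the neurogenesis list (aged LPS mouse 3, 0.0969). Without adult LPS mouse 3, 2 immediate-early genes fell. Adding 1 instead of 32 ended the calls of Map1b (0.0604), Wnk1 (0.0766) and Egr1 (0.119). The Egr1 call also ended with the arrays shifted to the same median (0.0603), without the filter on dim features (0.0580) and with only the groups compared in the fit (0.101), which ended that of Cldn5 too (0.0520).

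Markers of the olfactory bulb, a tissue that dissection can include in varying amounts, differed between the mice, and hepatocyte transcripts were high in some aged mice. Both lists were chosen after the data were seen. Cdhr1, a cadherin of bulb projection neurons, had a signal of 53.7 and 47.9 in adult saline mice 1 and 2, 87.1 in aged LPS mouse 2 and 44.6 in aged LPS mouse 3, and 178.6 to 249.6 in the other 8 mice. S100a5 was lower in the same 4 mice too (26.4 to 67 against 90.5 to 272.4), whereas Doc2g (69.6 to 138.7 against 126.4 to 200.5) and Eomes (57.1 to 94.7 against 75.5 to 217.7) overlapped between them and the other 8. With the mean level of 4 bulb markers as a covariate, LPS changed 74 features in adult mice and 19 in aged mice. In adult mice this ended the calls of Cxcl10 (2.93 ± 0.59 log2, adjusted p = 0.0953), Slco1a4 (-1.51 ± 0.27, 0.0569), Cx3cr1 (-1.32 ± 0.28, 0.109) and Cldn5 (-1.06 ± 0.26, 0.224), and that of the microglia marker list, whose median went from -0.49 to -0.40 (0.103). Over the 15 gene calls that it ended there, the change was 0.81 to 1.14 times that without the covariate, and its standard error 1.1 to 1.24 times. In aged mice Lcn2, Cebpd, Ifit1, Selp, Osmr, Usp18, Bcl3, Vcam1 and Cxcl12 still passed, whereas the other genes given above as called there had adjusted p between 0.0556 and 0.399. Over the 33 gene calls that it ended in aged mice, the change was 0.77 to 1.14 times that without the covariate, with a median of 0.95, and its standard error 1.28 to 1.40 times. It also ended the shifts of the complement list (median from 0.51 to 0.35, adjusted p = 0.0742) and the neurogenesis list (from -0.45 to -0.17, 0.217). Leaving out aged LPS mouse 3 and aged saline mouse 3 together, the 2 mice with the highest hepatocyte transcripts, left 62 features in aged mice. It ended the calls of Ramp2 (adjusted p = 0.0602), Map1b (0.0573), Slco1a4 (0.0888), Wnk1 (0.134), Egr1 (0.172), Ly6a (0.0619), Bcl3 (0.0595), Nfkbia (0.0720), Csf3 (0.0685), Cd14 (0.104) and S100a9 (0.0880), and those of the list of aged or activated microglia (median from 0.36 to 0.38, 0.111, and 0.0545 with the hepatocyte covariate) and the neurogenesis list (from -0.45 to -0.32, 0.143). Over the 20 gene calls that it ended in aged mice, the change was 0.69 to 1.19 times that with all mice, with a median of 1.02, and its standard error 0.95 to 1.33 times.

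Averaged over both ages, which used all 12 mice, LPS raised 296 features and lowered 294, of which 158 and 130 had symbols. Lcn2 rose by 4.75 ± 0.30 log2 (adjusted p = 7.24e-06), Cxcl11 by 3.46 ± 0.31, Gbp2b by 2.74 ± 0.24, Cxcl10 by 2.73 ± 0.34, Ccl12 by 2.66 ± 0.22 and Cebpd by 2.65 ± 0.17. Tlr2, a receptor for bacterial lipoproteins, rose by 0.99 ± 0.17 (adjusted p = 0.00705) and Fcgr3, an immunoglobulin receptor of myeloid cells, by 1.01 ± 0.18 (0.00930). Ptgs2, the inducible prostaglandin synthase, rose by 0.67 ± 0.15 (adjusted p = 0.0330). Ccl2 and Gfap did not pass, at 1.01 ± 0.24 (adjusted p = 0.0521) and 0.65 ± 0.21 (0.196). Of the interferon-stimulated genes, 18 of 23 rose, as did 12 of 13 glucocorticoid-responsive genes, including Fkbp5, a co-chaperone of the glucocorticoid receptor (1.04 ± 0.13), and 8 of 16 acute-phase genes. Adjusted over the list alone these counts were 22, 13 and 11. Of Toll-like receptor and NF-kB genes 7 of 12 rose, of endothelial activation genes 5 of 8, of reactive astrocyte genes 6 of 10 and of cytokines 2 of 4, with 12, 6, 7 and 4 adjusted over the list alone. These 7 lists passed with an estimated correlation too, at adjusted p between 0.0172 and 0.0426. The Ptgs2 call ended without any of 9 arrays (all but those of adult LPS mouse 1, adult saline mouse 1 and aged saline mouse 3), at adjusted p of 0.0534 to 0.0844, and after adding 1 instead of 32 (0.0841), with the bulb covariate (0.66 ± 0.15, 0.0577) or without aged LPS mouse 3 and aged saline mouse 3 (0.73 ± 0.17, 0.0811), which left 315 features and Fcgr3 at 0.95 ± 0.21 (adjusted p = 0.0746). The total of 590 was 389 without aged saline mouse 2 (237 rose and 152 fell), 323 after adding 1 and 947 with the intensity trend. The 294 falls also came to 154 and 189 without adult saline mice 2 and 3, 188 without adult LPS mouse 3, 182 and 172 without aged LPS mice 1 and 3 and 195 without aged saline mouse 1.

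Averaged over both ages, the genes that fell included brain endothelial markers and immediate-early genes. Cxcl12 fell by 1.83 ± 0.16 log2, Ppargc1a by 1.59 ± 0.15, Ramp2 by 1.56 ± 0.20, Map1b by 1.41 ± 0.19 and Wnk1 by 1.27 ± 0.17. Of 11 brain endothelial markers 7 fell and 1 rose, and 8 and 1 did adjusted over the list alone (camera adjusted p = 0.000518, and adjusted p = 0.0426 with an estimated correlation). They included Slco1a4 (-1.45 ± 0.16), Cldn5 (-1.28 ± 0.15) and Flt1, a receptor for vascular endothelial growth factor (-0.99 ± 0.14). Of 14 immediate-early genes 6 fell, including Egr1 (-1.28 ± 0.15), Nr4a1 (-1.14 ± 0.20) and Nr4a3 (-0.99 ± 0.11), and 9 did adjusted over the list alone (adjusted p = 5.04e-05, and adjusted p = 0.214 with an estimated correlation). Of 7 microglia markers 3 fell, Cx3cr1 (-1.11 ± 0.16), Gpr34 (-0.82 ± 0.18) and P2ry12 (-0.74 ± 0.15), and the list had an adjusted p of 0.0851. The Gpr34 call ended without any of 9 arrays (all but those of adult LPS mouse 2, aged LPS mouse 1 and aged saline mouse 2, adjusted p of 0.0521 to 0.0870) and the P2ry12 call without adult saline mouse 1, aged LPS mouse 1 or aged saline mouse 3 (0.0503 to 0.0531). Of 8 astrocyte markers, the bicarbonate transporter gene Slc4a4 (-1.21 ± 0.22) and the water channel gene Aqp4 (-0.96 ± 0.17) fell, and the list had an adjusted p of 0.0732. A dimmer probe set of Aqp4 gave 0.37 (adjusted p = 0.275), and with the mean of both probe sets Aqp4 had an adjusted p of 0.373. Kcne2, a potassium channel subunit of the choroid plexus, fell by 0.84 ± 0.13. Adding 1 instead of 32 ended the calls of Slc4a4 (0.0560), Kcne2 (0.0588), Gpr34 (0.105) and P2ry12 (0.0696).

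The upward shifts of the smaller immune lists averaged over both ages passed in camera with the preset correlation and not with an estimated one. In fry antigen presentation had an adjusted p of 0.115, and the other 4 had 0.000106 to 0.00138. Of 9 chemokine genes 4 rose and 1 fell, and 7 and 1 did adjusted over the list alone (camera adjusted p = 0.000319, and adjusted p = 0.145 with an estimated correlation). Of 3 neutrophil and monocyte markers, S100a8 (1.89 ± 0.24) and S100a9 (1.61 ± 0.16) rose (adjusted p = 0.00295, and adjusted p = 0.0740 with an estimated correlation). Of 7 complement genes 2 rose, C2 (0.83 ± 0.18) and C1qb, a subunit of the initiating complex of complement (0.62 ± 0.12), and 5 did adjusted over the list alone (adjusted p = 0.00377, and adjusted p = 0.158 with an estimated correlation). The C2 call ended without any of 8 arrays (adult LPS mice 2 and 3, adult saline mice 1, 2 and 3, aged LPS mice 1 and 3 and aged saline mouse 2, adjusted p of 0.0589 to 0.0827) and after adding 1 instead of 32 (0.0716). Of 12 genes of aged or activated microglia 2 rose, Fcgr3 and Fcgr2b (0.65 ± 0.11), and 5 did adjusted over the list alone (adjusted p = 0.0122, and adjusted p = 0.0881 with an estimated correlation). None of 9 genes of antigen presentation passed, and 1 rose adjusted over the list alone (adjusted p = 0.0475, and adjusted p = 0.431 with an estimated correlation). Of these H2-K1 gave 0.43 ± 0.17 (adjusted p = 0.298), while 2 other probe sets of this gene rose, by 0.99 and 0.64 (0.0255 and 0.0274). The antigen presentation shift ended without any of 7 arrays (adult LPS mice 1 and 3, adult saline mouse 1, aged LPS mice 2 and 3 and aged saline mice 1 and 2, adjusted p of 0.0513 to 0.143). It also ended with array weights (0.0738), with the arrays shifted to the same median (0.0557) and after adding 1 (0.0534). Without aged LPS mouse 3 and aged saline mouse 3, C1qb gave 0.57 ± 0.13 (adjusted p = 0.0925) and Fcgr3 0.95 ± 0.21 (0.0746).

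Between aged and adult mice given saline, no single gene passed. Among named genes the smallest p-values were those of C4, a complement component whose symbol the reference does not tie to a single gene, at 1.22 ± 0.21 log2 (adjusted p = 0.252) and Lyz2, a myeloid lysozyme, at 1.16 ± 0.20 (0.252). Lgals3, a lectin of activated phagocytes, gave 1.0 ± 0.23, Lyz1 0.67 ± 0.15 and Samsn1, an adaptor protein of immune cells, 0.66 ± 0.14, each at an adjusted p of 0.508. Gfap gave 0.86 ± 0.30 (adjusted p = 0.847) and Il1b 0.47 ± 0.16 (0.847). By limma 0 of 31385 features passed, the smallest adjusted p was 0.192, and 1642 had an unadjusted p under 0.05 where 1569 were expected. The unmoderated test also called 0, limma with an intensity trend and robust spread 4, and limma called 1 after adding 1 instead of 32 and 3 after adding 4 times as much as 32. The 3 aged mice lay above all 3 adult mice in 1753 features and below them in 1488, where chance gives 10% of the 31385 in all. Without adult saline mouse 3, 1 feature passed.

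The genes of aged or activated microglia lay higher in aged saline mice, although none of the 12 passed singly. Adjusted over the list alone 3 rose, and the median was 0.31 (camera adjusted p = 1.34e-05, and adjusted p = 0.0481 with an estimated correlation). The 14 immediate-early genes had a median of -0.37 (adjusted p = 1.34e-05, and adjusted p = 0.408 with an estimated correlation), with Npas4 at -0.81 ± 0.31 and Egr4 at -0.78 ± 0.25. The 4 pericyte and smooth muscle markers had a median of -0.37 (adjusted p = 0.00649, and adjusted p = 0.256 with an estimated correlation) and the 4 meningeal fibroblast markers one of 0.43 (adjusted p = 0.0115, and adjusted p = 0.256 with an estimated correlation). These shifts ended without adult saline mouse 1, at adjusted p of 0.0531 and 0.0995. The 7 complement genes had a median of 0.37 (adjusted p = 0.0115, and adjusted p = 0.408 with an estimated correlation). The 10 reactive astrocyte genes stood at 0.31 (adjusted p = 0.0330, and adjusted p = 0.510 with an estimated correlation) and the 9 genes of antigen presentation at 0.18 (adjusted p = 0.0330, and adjusted p = 0.666 with an estimated correlation). The 16 acute-phase genes and STAT3 targets stood at 0.24 (adjusted p = 0.0395, and adjusted p = 0.580 with an estimated correlation). In fry the list of aged or activated microglia had an adjusted p of 0.00891, and the other 7 lists had 0.104 to 0.514. Without adult saline mouse 1 or aged saline mouse 3 these last 4 shifts ended, at adjusted p of 0.0522 to 0.0788 for complement, 0.451 to 0.722 for antigen presentation, 0.0788 to 0.242 for astrocyte genes (also without aged saline mouse 1) and 0.0995 to 0.604 for acute-phase genes (also without adult saline mouse 2). Array weights ended the last 3 of them (0.0659 to 0.0950), adding 1 those of antigen presentation and acute-phase genes (0.0702 each), and leaving out the lowest 50% of the features that of acute-phase genes (0.0753).

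Transcripts made by hepatocytes were high in some of the aged brains beside these complement and acute-phase shifts. Of the 32 listed, chosen after the data were seen, 23 were tested and none passed (lowest adjusted p of 0.546). Their median age difference in saline mice was 1.23 log2. None is in a list fixed beforehand, and Itih3 was bright in all 12 brains, at 659.8 to 1031. Alb, which encodes serum albumin, had signals of 200.6, 295.1 and 518.8 in aged saline mice 1, 2 and 3 and of 53.7, 2.3 and 1423 in aged LPS mice 1, 2 and 3, against 15.9 to 73 in the 6 adult mice. Of the 23 transcripts, 14, 21 and 23 lay above the highest adult mouse in aged saline mice 1, 2 and 3, and 6, 3 and 23 in aged LPS mice 1, 2 and 3. The acute-phase genes Hp and Saa1 had 368.1 and 389.4 in aged LPS mouse 3 and 144.6 and 224.2 in aged saline mouse 3. Their highest adult values were 39.2 and 57.5. The complement gene C3 had 351.7 and 145 in the same 2 mice and 80.5 and 1.6 in aged LPS mice 1 and 2. Its highest adult value was 17.6. The mean level of the hepatocyte transcripts separated aged (6.30 to 7.56 log2) from adult saline mice (at most 5.76). As a covariate it can therefore absorb any age difference. With it the acute-phase list had a median of 0.07 in the saline comparison and the opposite camera direction (adjusted p = 0.917). Complement (median from 0.37 to 0.25, adjusted p = 0.461), antigen presentation (0.18 to 0.20, 0.369) and immediate-early genes (-0.37 to -0.19, 0.0597) no longer passed. Without aged LPS mouse 3 and aged saline mouse 3 the medians were 0.32 for complement, 0.32 for reactive astrocyte genes, 0.18 for antigen presentation and 0.14 for acute-phase genes, and these shifts ended (adjusted p of 0.1 to 0.449). With the bulb covariate the last 3 of these ended as well, at medians of 0.29, 0.25 and 0.25 (0.134 to 0.182), and so did the pericyte shift (-0.28, 0.0660).

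**Figure D2:**
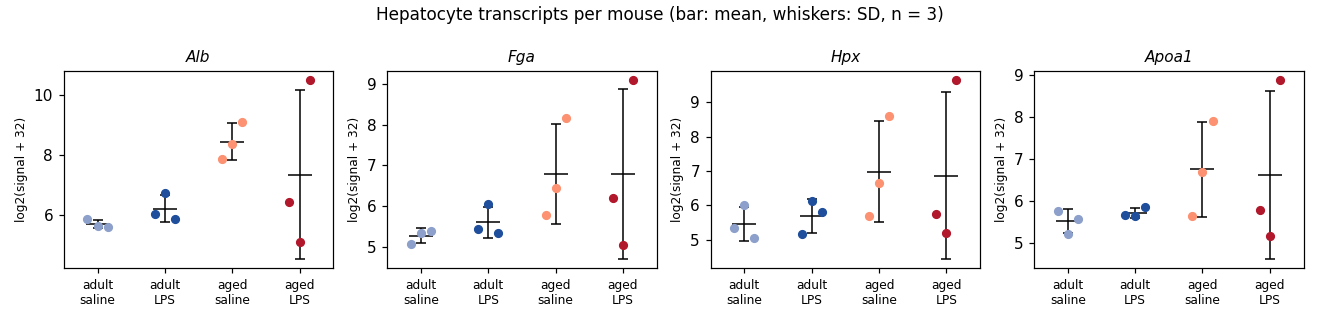
Each point is the log2(signal + 32) of 1 mouse for the hepatocyte transcripts Alb, Fga, Hpx and Apoa1 in the 4 groups. Alb reached 1423 in aged LPS mouse 3 and 518.8 in aged saline mouse 3, against 15.9 to 73 in the 6 adult mice.

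Between aged and adult mice given LPS, again no gene passed. Lyz2 stood at 1.07 ± 0.20 log2, C4 at 1.04 ± 0.21, the sorting receptor gene Sort1 at 0.94 ± 0.18, the transcription cofactor gene Lbh at 0.89 ± 0.16 and the chromatin protein gene Morf4l1 at -1.59 ± 0.32, each at an adjusted p of 0.513. Gfap gave 1.17 ± 0.30 (adjusted p = 0.578) and Il1b 0.56 ± 0.16 (0.578), with the 3 aged mice above the 3 adult mice for each, while Lcn2, Cxcl10 and Cd14 gave -0.25 ± 0.43, -0.23 ± 0.48 and -0.00 ± 0.24. By limma 0 features passed, with a smallest adjusted p of 0.513, and 2310 had an unadjusted p under 0.05 against 1569 expected. The unmoderated test called 0, the fit with an intensity trend 3, and adding 1 instead of 32 or 4 times as much as 32 gave 2 and 4. The aged mice lay above all adult mice in 2126 features and below in 2016, where chance gives 10% in all. The 12 genes of aged or activated microglia had a median of 0.33, and 2 rose adjusted over the list alone (camera adjusted p = 0.00425, and adjusted p = 0.152 with an estimated correlation), a shift that ended without adult LPS mouse 2 (0.0615). The 6 neurogenesis and proliferation genes had a median of -0.48, and 4 fell adjusted over the list alone (adjusted p = 0.00425, and adjusted p = 0.168 with an estimated correlation). The 5 pituitary and hypothalamic peptide genes had a median of -0.55, and 2 fell adjusted over the list alone (adjusted p = 0.00425, and adjusted p = 0.152 with an estimated correlation), with the vasopressin gene Avp at -1.30 ± 0.42. With the bulb covariate the neurogenesis list had a median of -0.20 and an adjusted p of 0.0627, and the microglia markers 0.31 and 0.219. Antigen presentation genes (0.34), glucocorticoid-responsive genes (-0.22) and microglia markers (0.40) each had an adjusted p of 0.0486, and adjusted p = 0.836, 0.694 and 0.312 with an estimated correlation. In fry the first 2 of these had an adjusted p of 0.383 each, and the other 4 lists of this comparison 0.00497 to 0.0464. These 3 shifts each ended without adult saline mouse 2 or aged saline mouse 1. Antigen presentation also ended without adult LPS mouse 1 or 2 or aged LPS mouse 2 or 3 (adjusted p up to 0.352), glucocorticoid genes without adult LPS mouse 3 or aged LPS mouse 1 (up to 0.338) and microglia markers without adult LPS mouse 2 or 3 or aged LPS mouse 1 or 2 (up to 0.119). With the hepatocyte covariate the 3 had medians of 0.27, -0.11 and 0.40 and ended too (adjusted p = 0.178, 0.126 and 0.0709), and antigen presentation ended without aged LPS mouse 3 and aged saline mouse 3 together (0.30, 0.119). All 3 also missed with the arrays shifted to the same median, with the lowest 50% of the features left out, with the mean over probe sets and without the filter on dim features (0.0501 to 0.0790). Adding 1 ended antigen presentation and glucocorticoid genes (0.0978 each), array weights glucocorticoid genes and microglia markers (0.0615 and 0.0598), quantile normalization glucocorticoid genes (0.0869) and adding 4 times as much as 32 microglia markers (0.0808).

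Averaged over treatment, C4 and Lyz2 were higher in aged mice, by 1.13 ± 0.15 and 1.12 ± 0.14 log2 (adjusted p = 0.0342 each), with each aged mouse above each adult mouse of the same treatment. They were the named genes among 4 features that passed, 3 higher and 1 lower. That count came to 0 without adult LPS mouse 1, adult saline mouse 1, aged LPS mouse 1 or 3 or aged saline mouse 2, to 1 without aged saline mouse 1 and to 2 without adult LPS mouse 2. Igk-V28, an immunoglobulin gene segment, gave 1.27 ± 0.22 (adjusted p = 0.273), Sgpl1, a lyase of sphingosine phosphate, 0.79 ± 0.14 (0.273) and Gfap 1.02 ± 0.21 (0.355). Of the 12 genes of aged or activated microglia 1 rose, Lyz2, and 6 did adjusted over the list alone (median 0.32, camera adjusted p = 2.75e-05, and adjusted p = 0.0484 with an estimated correlation). The medians were 0.39 for antigen presentation, 0.27 for complement, 0.25 for reactive astrocyte genes, 0.24 for microglia markers and 0.25 for acute-phase genes, with adjusted p of 0.0124, 0.0186, 0.0186, 0.0436 and 0.0497. They were -0.17 for immediate-early genes, -0.24 for neurogenesis genes and -0.38 for peptide genes, with adjusted p of 0.0124, 0.0445 and 0.0447. For these 8 lists it was adjusted p = 0.335 to 0.503 with an estimated correlation and 0.0542 to 0.337 in fry, where the list of aged or activated microglia had 0.000486. With 1 array left out the C4 call ended for 9 arrays (all but those of adult LPS mouse 3, aged LPS mouse 2 and aged saline mouse 3, adjusted p of 0.0927 to 0.162) and the Lyz2 call for 11 (all but that of adult saline mouse 2, 0.0522 to 0.162), and the 8 lists each ended for 3 to 8 arrays, drawn from all but that of aged LPS mouse 2, at adjusted p up to 0.266. Adult saline mouse 1 and aged saline mouse 3 were among them for each list. With the hepatocyte covariate, which partly follows age, no feature passed. C4 and Lyz2 stood at 1.15 ± 0.20 and 1.20 ± 0.19 (adjusted p = 0.354 and 0.192). The acute-phase list had a median of 0.05 with the opposite camera direction (adjusted p = 0.940). The covariate also ended the shifts of complement (0.20, adjusted p = 0.474), antigen presentation (0.23, 0.196), microglia markers (0.24, 0.196), immediate-early genes (-0.04, 0.588), neurogenesis genes (-0.27, 0.196) and peptide genes (-0.20, 0.235). Without aged LPS mouse 3 and aged saline mouse 3 all 8 shifts ended, at adjusted p of 0.0921 to 0.620. Array weights ended those of acute-phase, immediate-early and peptide genes and microglia markers (0.0501 to 0.0669), and adding 1 or taking the mean over probe sets ended those of acute-phase, neurogenesis and peptide genes (0.0567 to 0.138). The acute-phase shift also ended with the lowest 50% of the features left out (0.128) and without the filter on dim features (0.0529), and the peptide shift with the arrays shifted to the same median (0.0509). C4 and Lyz2 also missed the threshold after shifting the arrays to the same median (0.0501 each), without the filter on dim features (0.0501 each), after adding 1 (0.156 and 0.152), with the bulb covariate (0.0758 and 0.0691) and without aged LPS mouse 3 and aged saline mouse 3 (0.120 each), with differences of 1.1 to 1.30 under all 5.

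The test of the difference between the aged and the adult LPS effect, which addresses the study's question directly, passed for no gene. Lcn2 differed by -1.15 ± 0.61 log2 (adjusted p = 0.953), Cxcl10 by -0.52 ± 0.68 (0.977), and Il1b by 0.09 ± 0.23 (0.987). Among named genes the smallest p-values belonged to Tjp3, a tight junction protein (-1.51 ± 0.32, adjusted p = 0.676), the activin receptor gene Acvr1 (0.88 ± 0.19, 0.744), Lbh (0.98 ± 0.23, 0.817), Samsn1 (-0.83 ± 0.20, 0.817) and Dlx1, a transcription factor of interneuron precursors (-1.10 ± 0.28, 0.851). By limma 0 of 31385 features passed and 1627 had an unadjusted p under 0.05, against 1569 expected. The unmoderated test and the fit with an intensity trend called 0 as well. The median standard error of a difference was 0.279 log2, and in simulated data of this design 0% of 1.5-fold, 16.4% of 2-fold and 74.2% of 4-fold differences were recovered.

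For 4 lists the difference of the LPS effect between the ages passed with the preset correlation, at a camera adjusted p of 0.0189 each, and for none with an estimated correlation. The 13 glucocorticoid-responsive genes had a median difference of -0.29 (adjusted p = 0.687 with an estimated correlation), with Pdk4, an inhibitor of pyruvate oxidation, at -0.90 ± 0.28 and Cdkn1a at -0.67 ± 0.31. The 14 immediate-early genes had one of 0.38 (adjusted p = 0.699 with an estimated correlation), with Egr4 at 0.88 ± 0.36 and Fosb at 0.73 ± 0.26. The 6 neurogenesis genes had -0.54 (adjusted p = 0.332 with an estimated correlation), with Dlx1 above and Dcx, a protein of migrating neuroblasts, at -0.68 ± 0.29, and the 5 peptide genes -0.83 (adjusted p = 0.240 with an estimated correlation), with Avp at -1.14 ± 0.59 and Trh at -0.99 ± 0.42. No member passed, and adjusted over the list alone 1 neurogenesis gene fell. The fry test, which asks whether a list moves on balance, gave adjusted p of 0.416, 0.416, 0.196 and 0.0456 in this order. The shifts ended with 1 array left out, for glucocorticoid genes without adult LPS mouse 3, aged LPS mouse 1 or aged saline mouse 1 or 2 (adjusted p of 0.0724 to 0.136), for immediate-early genes without adult LPS mouse 1 or 2, adult saline mouse 1, aged LPS mouse 1 or aged saline mouse 3 (0.0555 to 0.233), for neurogenesis genes without adult LPS mouse 2, adult saline mouse 2, aged LPS mouse 3 or aged saline mouse 3 (0.0532 to 0.0841) and for peptide genes without adult LPS mouse 3 (0.0614). The shift of the immediate-early genes also ended after adding 1 instead of 32 (0.0693). With the bulb markers as a covariate the neurogenesis and peptide lists had medians of -0.03 and -0.29 and adjusted p of 0.533 and 0.261. The mean log2 level of the bulb markers was 6.60 and 6.65 in adult saline mice 1 and 2 and 6.58 and 6.64 in aged LPS mice 2 and 3, against 7.30 to 7.78 in the other 8 mice.

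The adult and the aged LPS effects, which share no arrays, correlated across the 31385 features at r = 0.371 (Spearman 0.226), as a description across genes that are not independent replicates. Of the features called, 84 rose at both ages, against 0.510 for independent lists, and 13 fell at both, against 0.0647, and none moved in opposite directions. Of the 178 features called in adult mice 175 had the same sign in aged mice, and of the 170 called in aged mice 164 had the same sign in adult mice. Of the named genes 52 passed at both ages, 46 in adult mice alone, Cxcl1 by the probe set used here, and 31 in aged mice alone, a split that no test of the difference bore out for any gene. Of the 296 features that rose averaged over age, 124 had the larger rise in aged mice and 172 in adult mice, with medians of 0.92 and 0.96. Of the 294 that fell, 177 had the larger fall in aged mice, with medians of -0.81 in aged and -0.69 in adult mice. The correlation was 0.230 after adding 1 instead of 32 and 0.0812 with the bulb covariate. The age effects in saline and in LPS mice correlated at r = 0.0962.

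**Figure D3:**
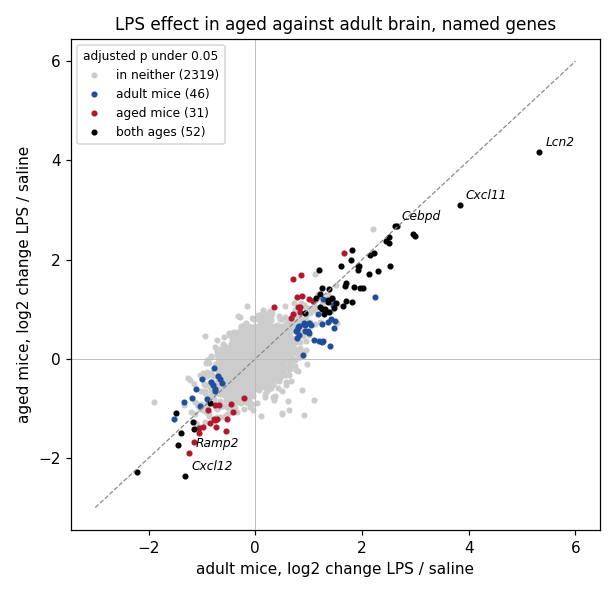
Each point is a named gene, with its LPS log2 fold change in adult mice on the x axis and in aged mice on the y axis, coloured by the age at which it passed. The 52 genes that passed at both ages lie where both changes have the same sign, and 2319 genes passed at neither age.

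The authors' deposited table for LPS in adult mice lists 1357 probe sets, 628 higher and 729 lower, with Lcn2 at a fold of 48.6. In the refit of the arrays 98.4% of them had the same direction in adult mice, and 48.5% also had an unadjusted p under 0.05. Of the 178 features called in the refit 96 were listed there. The authors' deposited table for LPS in aged mice holds the same values as the adult one for all 1357 probe sets, so it gives no separate account of aged mice, and in the aged arrays 84.4% of its probe sets had the listed direction. The authors' deposited table for age in saline mice lists 459 probe sets, 214 higher and 245 lower, and 98.0% had the same direction in the refit. Its folds include Alb at 10.5, Apoa2 at 3.92, Hpx at 3.21, Lyz2 at 2.60 and C4 at 2.53. The authors' deposited table for age in LPS mice lists 1390, 840 higher and 550 lower, of which 98.3% had the same direction, with Alb at 3.66, Fga at 3.46, Lyz2 at 2.55 and Gfap at 2.33. These directions come from the same arrays, so they are no independent evidence.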

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

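The tests of the hepatocyte transcripts and of RNA quality as read from control probe sets were chosen only after the result was seen, whereas those of the bulb markers, of covariation and of other splits of the mice were set before their own results were seen, the bulb marker list and covariate being chosen after the data were examined. The requirement that a relation between mice also pass a permutation test was added after its results were seen.

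A test of the difference between the aged and the adult LPS effect marked 4 gene lists for a closer look, at the preset correlation. The median difference was -0.286 log2 for glucocorticoid genes, 0.382 for immediate-early genes, -0.537 for neurogenesis genes and -0.835 for peptide genes. None of them passed with an estimated correlation. Without aged LPS mouse 3 and aged saline mouse 3 the camera adjusted p was 0.00104, 0.0771, 0.155 and 0.0228 in this order.

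The lower neurogenesis and peptide genes in aged LPS brains may come from what tissue was dissected or from an LPS response that differs with age. Bulb content was tested, hypothalamus and pituitary content was not. Between mice of the same group, the bulb markers and the neurogenesis genes correlated over 12 mice at r = 0.5625 (permutation p = 0.0941, rho = 0.615, permutation p = 0.0640, Benjamini-Hochberg adjusted p of 0.242 for r and 0.166 for rho over 5 relations), and at 0.275 without the 2 mice farthest in bulb markers, so the relation rests on those mice. The value of r reached the preset 0.5, and the missed permutation test leaves it open. The peptide genes gave r = 0.4548 (permutation p = 0.110, rho = 0.483, permutation p = 0.151, 0.462 without the same mice). With the bulb markers as a covariate the neurogenesis list had an adjusted p of 0.533. Its median difference was -0.03, inside the preset 0.2 by less than the standard error. Its mean moved from -0.46 ± 0.17 to -0.17 ± 0.23, which ends the call without excluding an effect of age. For these lists tissue content and an age-dependent response cannot be told apart.

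Hepatocyte transcripts were high in 4 of the 6 aged brains, and may come from liver tissue or RNA carried into the samples or from expression that comes with age. Over the 23 transcripts aged LPS mouse 3 and aged saline mouse 3 correlated at r = 0.8958. Adult pairs reached 0.807 to 0.949, so this decides nothing. The excess of these 2 mice over the adult mean correlated at r = 0.913, as a shared source would give. Adult pairs (-0.472 to 0.365), unlike aged ones, enter that mean, so they are no like comparison. All 23, partly selected as high in aged mice, lay above the highest adult mouse in both. The 5 pairs with aged saline mouse 1 or 2 gave 0.343 to 0.568 (median 0.4604), under the 0.7 asked of one source. For saline mice 1 and 2 liver content stays open. Of the 6 aged mice 5 lay above the highest adult mouse in mean level (5.93 log2), aged LPS mouse 2 lay at 5.70 and aged LPS mouse 1 barely above at 5.94, which rests on 1 array and excludes no expression that comes with age. A change with age in some brains alone was not tested.

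The 294 features that fell after LPS, with Map1b and Wnk1 among them, may reflect array-to-array variation in RNA preparation or a response whose size differs between mice. In saline mice alone the set covaried between mice at a mean pairwise r of 0.0806, above the 0.00628 that bounds 95% of random sets, so a variation that is independent of LPS acts on these features too, though it is not particular to them (0.0187 for the features that rose, bound 0.01) and the set covaried more in LPS mice (0.256, bound 0.00913). In LPS mice the set and the features that rose correlated over 6 mice at r = -0.8014 (exact permutation p = 0.306, rho = -0.60, exact permutation p = 0.444, and -0.325 without the 2 farthest mice), which met the value set before it was seen, and between mice of the same group the set and the 18S control correlated over 12 mice at r = 0.5225 (permutation p = 0.145, rho = 0.573, permutation p = 0.0664, and 0.203 without adult LPS mouse 3 and aged LPS mouse 3), so both relations rest on their 2 farthest mice and stay open. The test of a 3' bias of the RNA asked for every LPS array to lie above every saline array, which neither control gene met. Of the 6 LPS arrays 0 had an actin 3'-to-5' ratio above every saline array. For Gapdh 1 of the 6 did, adult LPS mouse 3 (0.919 against at most 0.871). The ratios of 2 control transcripts cannot exclude a smaller bias or one in other transcripts, so a 3' bias stays open. RNA degradation or preparation that lowers 18S is not excluded either, with 4 of the 6 below every saline array (88.1 to 190.6 against at least 195.5). An LPS effect on the set is not excluded by this covariation, and Wnk1 lay at 145.4 to 367.8 in the 6 LPS mice and at 440 to 621.9 in the 6 saline mice, whereas Map1b reached 496.6 in 1 LPS mouse and was 495.5 in 1 saline mouse.

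Other splits of the same mice were run for each count of features. For comparisons of 3 against 3 mice the 10 splits are too few for a share under 0.05. The real split gave 178 for LPS in adult mice, where the highest other gave 0 (1 of 10 splits as large), 170 in aged mice, where the highest other gave 0 (1 of 10), 0 for age in saline mice, where the highest other gave 1 (10 of 10), and 0 for age in LPS mice, where the highest other gave 0 (10 of 10). Of 100 splits within the strata, 1, the real one, gave as many as the 590 features of the averaged LPS effect (highest other 4). Likewise 1 gave as many as the 4 features of the averaged age effect (highest other 2). Both shares lie under 0.05. Most other splits mix the groups compared, so a real effect widens their spread and lowers their counts. For age the margin is small and the count came to 0 with some single arrays left out, so chance is not excluded for it. For the difference of the LPS effect all 100 splits gave at least the real 0 (highest other 4), which any split must, so this count decides nothing.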

How the results depend on the processing

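The removal of the 2 arrays together and the covariates of hepatocyte transcripts and bulb markers were chosen after seeing the data, and all other alternatives were set beforehand. Over all alternatives and left-out arrays, 3409 values of called genes kept direction and call, 404 lost the call and none turned. Of called lists 1710 kept theirs, 270 lost it and 2 turned. Of 147 gene calls a pseudocount of 1 ended 52, the bulb covariate 51 and the removal of the 2 arrays 36, and of 71 list calls camera with an estimated correlation ended 53, fry 22 and the removal of the 2 arrays 17. A pseudocount of 1 ended 27 of 72 gene calls below their median signal and 25 of 75 at or above it. Unless stated, the cause was not tested.

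With arrays shifted to the same median, 2 features passed for age averaged over treatment, with 50% of them higher in place of 75%. A pseudocount of 1 gave 83 features for LPS in adult mice, 84 in aged mice, 323 averaged, 1 and 2 for age in saline and LPS mice and 1 averaged, 9 calls of stated genes in place of 14, and an agreement of LPS effects of r = 0.230. A pseudocount 4 times as large as 32 gave 364, 501, 984, 3, 4 and 14 features and r = 0.454. Without the dim filter the averaged age count was 2 and r 0.290. With the lowest 50% left out, which leaves fewer features to adjust over, 290 passed for LPS in aged mice and r was 0.486. With an intensity trend and robust spread the counts were 318, 451, 947, 4, 3 and 14. With only the groups compared 113 passed in adult mice. The unmoderated test gave 66, 42 and 308 for LPS and 1 for age averaged.

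Without aged LPS mouse 3 and aged saline mouse 3, 62 features passed for LPS in aged mice, 315 averaged and 0 for age averaged, with r = 0.337 and fewer mice. With the hepatocyte covariate, which partly follows age, 0 passed for age averaged. The acute-phase list turned direction for age in saline mice (median 0.0725, camera adjusted p = 0.917) and averaged (0.0489, 0.940). Its medians stayed above 0. With the bulb covariate 74 passed for LPS in adult mice, 19 in aged mice and 2 for age averaged, with r = 0.0812. Error in the slope that both LPS effects then share pulls this r down.

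With each array left out in turn, LPS changed 89 to 175 features in adult mice, 72 to 287 in aged mice and 389 to 567 averaged. Age changed 0 to 1 in saline mice, 0 to 0 in LPS mice and 0 to 4 averaged, and the difference of the LPS effect 0 to 0. Calls of stated genes numbered 11 to 15, list shifts 57 to 72, r lay at 0.267 to 0.391, and the share of listed probe sets with the authors' direction at 96.2% to 98.1%.

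The shared mouse numbers do not pair the mice. Deviations of mice with the same number correlated at -0.07 to 0.11 over 18 pairs, with a mean of 0.00858, against a mean of -0.00429 for different numbers. With the number as a replicate block, 144, 147 and 527 features passed for LPS in adult mice, aged mice and averaged, 0 for age in either treatment and for the difference, and 1 for age averaged, and 138 of 147 calls of genes and 69 of 71 of lists were kept, those of C4 and Lyz2 for age averaged not among them (0.134 each).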

Other observations

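The tests of the authors' age lists and of a larger rise in aged mice were chosen only after the result was seen.

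The following lists passed camera in no comparison. For LPS averaged over age, neuron markers had a median of -0.04 log2 over 4 tested genes of 16 (camera adjusted p = 0.790). Oligodendrocyte and myelin markers had -0.09 over 7 of 16 (0.592), and redox genes -0.00 over 7 of 18 (0.957). Of 5 collagen and extracellular matrix genes 1 rose, the basement membrane gene Col4a1 (0.69 ± 0.14, adjusted p = 0.0199), and the list had an adjusted p of 0.295. The Col4a1 call ended without adult saline mouse 2 or 3 or aged LPS mouse 3, at adjusted p of 0.0514 to 0.0573, after adding 1 instead of 32 (0.0525) and without aged LPS mouse 3 and aged saline mouse 3 (0.62 ± 0.15, 0.0945). The first principal component over all features held 19.6% of the variance, and adult LPS mice 1 and 2 stood at 0.95 and 4.82 on it, apart from adult LPS mouse 3 at 32.6 and the aged LPS mice at 24.7 to 31.99.

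Whether brains of aged mice respond to LPS with a larger rise was put as a hypothesis to the 296 features that rose. The mean LPS effect over this set was -0.09 log2 in aged minus adult mice, and the fry test of limma gave it p = 0.4444 and a two-sided exact permutation test of age within treatment over 400 assignments p = 0.39. A larger rise in aged mice was thus not shown, and not excluded.

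A hypothesis that may be put is age differences shared by saline and LPS mice. Of the probe sets in the authors' deposited table for age in saline mice, 66.4% had the same direction in LPS mice, which 1 of the 20 assignments of the 6 LPS mice reached, the real one (highest other 64.5%). This table lists 22 of the 32 hepatocyte transcripts as higher, and without hepatocyte transcripts the share was 64.8% (1 of 20 assignments, highest other 63.2%). The list for age in LPS mice had the same direction in saline mice for 63.7%, which 5 of 20 assignments reached (highest other 78.1%), so the hypothesis, which asked for both, stays open.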
